A study of Mus musculus with 4 samples.

How the data were processed

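Total RNA from mouse liver was extracted with Trizol and made into Illumina sequencing libraries, per the labels' protocols. Base calling with CASAVA 1.8, alignment with HISAT2 2.1.0 to the mm10 build and counting with HTSeq are named per the submitters' processing notes, which give no roles or order; the use given here for each tool is its usual one. The HTSeq version, the annotation, the read length, the strand setting and any trimming are not given in the sources used here. The deposited files hold 1 raw count per gene symbol for each of the 4 libraries, as whole numbers with no normalization, made by the authors before deposit. Each file lists 25239 genes and closes with 5 rows that name no gene. These rows stayed out of library sizes and tests. Alignments to more than 1 place took 6.70% and 9.03% of all records in the control libraries and 5.18% and 5.33% in the extract libraries, and records in no annotated feature took 8.40%, 10.2%, 8.88% and 9.79% in the same order. Records on more than 1 gene took 1.01%, 1.22%, 1.02% and 0.989%, low-quality alignments 0.556%, 0.733%, 0.702% and 0.669%, and unaligned records 0.552%, 0.776%, 0.675% and 0.663%. Genes with near-identical copies can therefore lose reads to the class with no unique place. Without a stated strand setting, reads of overlapping antisense genes cannot be told apart. Gene positions come from RefSeq on GRCm38.p6, the same assembly as mm10, by symbol, which matched 99.22% of the genes.

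Groups follow the sample titles, with 2 control and 2 extract libraries. Counts were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling, a robust dispersion estimate, glmQLFit with robust fitting and a 2-sided quasi-likelihood F test, adjusted after Benjamini and Hochberg over the 13963 genes kept, with a threshold of 0.05. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 22.3%. One read is worth 0.0208, 0.0337, 0.0232 and 0.0210 CPM in the 4 libraries, and a count of 0 allows up to 0.0625, 0.101, 0.0696 and 0.0630 CPM (3 counts), for counting error only. The chi-square over its degrees of freedom was 118 for the control pair and 29.1 for the extract pair, so the libraries of a group differ by more than sampling noise. Before the data were examined, 41 gene lists with 923 members were fixed, of which 900 members were found by symbol or RefSeq synonym. The lists with at least 3 tested members, 38 in all, were tested with limma 3.58.1's camera at an inter-gene correlation of 0.01 and again with an estimated correlation, and with fry, each adjusted over the 38 lists. With an estimated correlation camera takes its degrees of freedom from the 4 libraries and not from the genes, so few lists can pass. Mitochondrially encoded genes had 0 members among the gene symbols, pancreatic acinar genes had 2 tested members with 0 past the threshold, and Y-linked genes were read only as counts. In the closing section, intervals of list medians come from 10000 bootstrap resamples of the members. Stretches of 75 bases of the Sult2a and Serpina1 genes were compared over all transcripts of GENCODE vM21, on GRCm38, on both strands.

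Named genes were chosen by a rule fixed before the data were examined. Adamts13 and Vwf were always named. The rule then took the 12 genes with the largest log2 fold change in each direction among those past the threshold, with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted genes and pseudogenes. From each list described it took up to 4 members with the smallest p-values and a mean of at least 1 CPM, and up to 2 called members of the opposite direction. A gene that the rule takes is not reported here. The alternatives tried were other scalings (DESeq2's size factors, upper quartile, total counts), DESeq2 1.42.0, limma-voom, a fit without the robust step, no filter and a strict filter on low counts (at least 10 counts in at least 2 libraries and a mean of 1 CPM), leaving out the 20 most abundant genes, leaving out each library, a replicate block, a minimum fold of 1.5 and other list tests. The genes to test were chosen anew in each fit, so the genes and list members tested can differ from the main fit. Without control replicate 2, for example, 14592 genes were tested.

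The edgeR step was tested on simulated counts for 13963 genes, drawn from the means, library sizes and dispersions of the real libraries, with 2 libraries per group. Of 50 genes changed 8-fold it recovered 86% (43 genes), and of 50 changed 4-fold 80% (40 genes). Of 50 changed 2-fold it recovered 38% (19 genes), and of 50 changed 1.5-fold 0%. It also called 18 of the unchanged genes, so false calls took a larger share of the simulated calls than the adjusted p threshold implies. The calls on the real libraries can therefore hold more false ones than that threshold implies. Camera called a simulated list of raised genes higher and 0 of 30 lists of unchanged genes. Each gene was drawn independently, so this does not test camera's calls on lists whose members are correlated. A difference of 2-fold or less was thus often missed in the simulation and can go undetected here. The simulation changed far fewer genes than the 1193 called in the real libraries, and gave both groups the same dispersion. Its shares therefore need not hold for the real libraries, where some smaller differences were called, such as Gpt (1.67-fold).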

Results

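Liver RNA was sequenced from C57BL/6 mice given saline (control) or an extract of Gynura segetum by stomach tube, at 30 g/kg per day for 3 weeks from an extract concentrated to 2 g/mL. Gynura segetum is a medicinal plant that contains pyrrolizidine alkaloids, which liver cytochrome P450 enzymes turn into reactive pyrroles and which injure the endothelium of the hepatic sinusoids. The series holds 2 control and 2 extract libraries. Reads counted to genes came to 49711750 and 32215268 in the control libraries and to 40013188 and 45754235 in the extract libraries, over 25239 genes. The labels do not say that the libraries come from separate mice, so the p-values measure only the spread between these samples, which may be technical. Collection times are not given either, so a difference between the groups can include a difference in time of day. The title of the series names Adamts13, the plasma protease that cleaves von Willebrand factor, and platelet accumulation, and the comparison asks how the liver transcriptome differs after the extract.

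The libraries separated by treatment. On a scale of log2(CPM + 1), the extract pair correlated across genes at r = 0.997 and the control pair at r = 0.990, while pairs of libraries from different groups gave r from 0.979 to 0.982. Genes are not independent replicates, so these values only describe the libraries. The first principal component, with 68.2% of the variance, parted control from extract, and the second, with 23.1%, parted the control libraries from each other. Albumin (Alb) took 10.2% and 10.1% of the gene counts in the control libraries and 7.47% and 7.77% in the extract libraries.

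After the extract, many targets of p53 and enzymes of glutathione conjugation rose, and many markers of Kupffer cells, the resident macrophages of the liver, and of sinusoidal endothelium fell. On these 4 lists, 23 of 32 p53 targets and 16 of 29 Nrf2 and glutathione genes were higher, and 12 of 16 Kupffer cell and 9 of 18 sinusoidal markers were lower, each list with an adjusted p = 0.178 with an estimated correlation. Of 13963 genes tested with edgeR's quasi-likelihood test, 686 were higher and 507 lower at an adjusted p under 0.05, and 491 and 364 of these differed at least 2-fold. The p53 target Phlda3, an inhibitor of Akt signalling on chromosome 1 (positions 135766085 to 135769134, mm10), went from 1.59 ± 0.18 to 138.5 ± 3.74 CPM (SD, n = 2 libraries each; log2 fold change 6.46, SE 0.18, edgeR adjusted p = 8.29e-05). Vsig4, a complement receptor of Kupffer cells on chromosome X (96247201 to 96293438), went from 44.4 ± 4.76 to 1.89 ± 0.054 CPM (log2 fold change -4.55, SE 0.18, edgeR adjusted p = 0.000196). Serpina1e, a member of the alpha-1-antitrypsin family on chromosome 12 (103946931 to 103956897), went from 1988 ± 150.2 to 39.5 ± 4.33 CPM (log2 fold change -5.65, SE 0.19, edgeR adjusted p = 0.000105). The groups did not overlap for 54.4% of the genes tested, where chance gives 33.3%.

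Besides Phlda3, the largest increases among genes of at least 5 CPM were in Inka2 (log2 fold change 8.32), the cytokine Lif (7.91, from 4 counts in the control libraries), the sarcomere protein Myom3 (6.97), the peptide hormone Apln (6.88), Cox6b2 (6.69), Prrg4 (6.35), the death receptor Tnfrsf10b (6.35), Mybl1 (6.04), the clock output factor Dbp (6.04) and the ectodysplasin receptor Eda2r (5.86). Zfp365 had 0 counts in the control libraries and 1180 in the extract libraries, at least 161-fold higher when each control library is set at 3 counts. The largest decreases besides Serpina1e and Vsig4 were in the sulfotransferases Sult2a1 (-6.16), Sult2a5 (-5.84) and Sult2a2 (-5.42), the Kupffer cell genes Timd4 (-5.33), Clec4f (-4.86) and Cd163 (-3.94), the clock factor Npas2 (-4.68), the bile acid 12-alpha-hydroxylase Cyp8b1 (-4.28), Sugct (-3.86) and the deiodinase Dio1 (-3.84). Members of the Sult2a and Serpina1 families share stretches of sequence, so their counts are less certain than those of single-copy genes. The number of calls depended on which libraries were used. It came to 1826 higher and 1420 lower without control replicate 1, 1809 and 1782 without control replicate 2, 233 and 134 without extract replicate 1, and 310 and 169 without extract replicate 2. A lone library was assumed to vary like the pair of the other group, and the extract pair was the tighter one. Apln, Dbp and Dio1 were not past the threshold with either extract library left out, and Sult2a2 was not past it with either control library left out.

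Adamts13 was lower after the extract in both libraries but did not pass the threshold over all genes. The gene lies on chromosome 2 (26973361 to 27009625, mm10). Its counts were 540 and 232 in the control libraries and 176 and 242 in the extract libraries, or 9.53 ± 2.44 against 4.58 ± 0.71 CPM (SD, n = 2 libraries each; log2 fold change -1.06, SE 0.27, edgeR adjusted p = 0.064, unadjusted 0.00635). DESeq2's Wald test gave -1.06 with an adjusted p of 0.0125, and the edgeR fit without a filter on low counts gave -1.05 with 0.0237, while the adjusted p ran from 9.69e-06 to 0.403 over all alternatives. It was 0.032 without control replicate 1 (log2 fold change -0.77), 9.69e-06 without control replicate 2 (-1.29), 0.403 without extract replicate 1 (-0.92) and 0.194 without extract replicate 2 (-1.24). Vwf, which encodes the substrate of the protease, lay at 5.28 ± 1.86 CPM in control and 5.50 ± 3.53 CPM in extract libraries (log2 fold change 0.06, SE 0.51, edgeR adjusted p = 0.963).

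**Figure D1:**
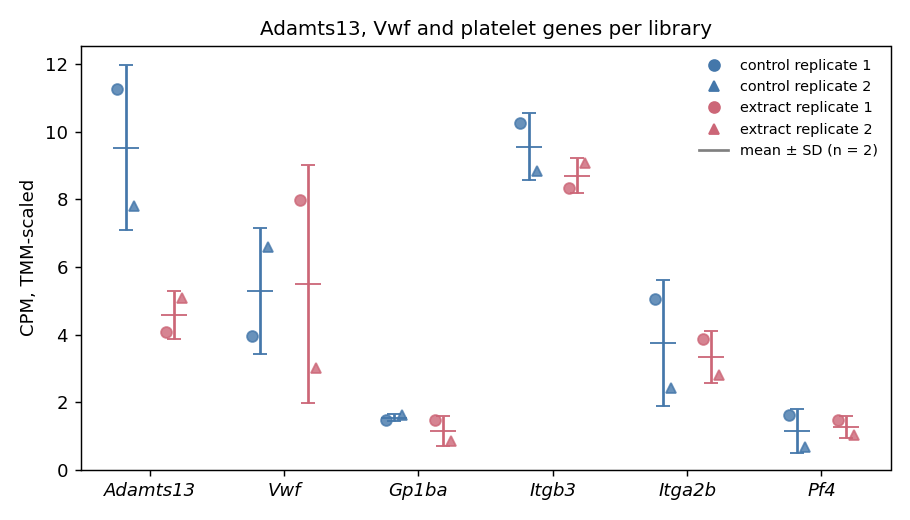
TMM-scaled CPM (vertical axis, from 0) of Adamts13, Vwf and 4 platelet genes in each library, with points for the 2 control (blue) and 2 extract (red) libraries and the group mean ± SD (n = 2). Adamts13 lies at 11.3 and 7.81 CPM in the control libraries and at 4.08 and 5.08 CPM in the extract libraries, and the groups overlap for Vwf.

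Platelet and megakaryocyte transcripts were scarce, and no difference between the groups was detectable in them. Of 14 genes on the list, 5 had enough counts to be tested with edgeR, and 0 were past the threshold, over all genes or adjusted over the list alone. Log2 fold changes were 0.12 for Pf4 (platelet factor 4), -0.18 for Itga2b (integrin alpha IIb), -0.14 for Itgb3 (integrin beta 3) and -0.42 for Gp1ba, the von Willebrand factor receptor. The list median was -0.18 (camera adjusted p = 0.749, adjusted p = 0.906 with an estimated correlation). It turned to 0.89 without control replicate 1 and to 0.04 without extract replicate 2, and was -0.34 without control replicate 2 and -0.30 without extract replicate 1. At an unadjusted p under 0.05 the count was also 0, with unadjusted p from 0.423 to 0.841 over the 5 genes, and DESeq2 and limma-voom called 0 members. Platelets carry little RNA, and transcripts in whole liver do not count platelets.

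Genes of the von Willebrand factor axis and of endothelial haemostasis went in both directions. Thrombomodulin (Thbd, 2.46), tissue plasminogen activator (Plat, 2.85) and endothelial nitric oxide synthase (Nos3, 1.54) rose on the log2 scale, and coagulation factor VIII (F8, -1.51) fell. Of 15 members tested, 3 were higher, 1 lower and 11 not past the threshold, or 4 higher and 2 lower adjusted over the list alone. The median was 0.92 (camera adjusted p = 0.0539, adjusted p = 0.787 with an estimated correlation). Without control replicate 1 the camera adjusted p was 0.000561, with 9 members higher and 2 lower and a median of 1.60, and without extract replicate 2 it was 0.00769, with 2 and 0. Without control replicate 2 there were 5 and 2 with a median of 0.47, and without extract replicate 1 there were 1 and 0. It was also past the threshold with upper-quartile scaling (0.0425), without the robust step (0.0476), without a low-count filter (0.0302) and without the 20 most abundant genes (0.0467).

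Of the 38 gene lists tested with camera, 7 were higher and 11 lower relative to other genes at an adjusted p under 0.05. With an estimated correlation 0 lists were called, with a lowest adjusted p of 0.178 and 6 lists at an unadjusted p under 0.05. Several lists share 0.178 through the adjustment, with unadjusted camera p from 0.00787 (Nrf2 targets) to 0.0235 (female-biased genes). With 4 libraries that setting lets few lists pass, so a lost call does not show that correlation between members had made it. By fry, which asks whether a list's genes move one way on balance, 2 lists were higher (p53 targets and Nrf2 targets) and 3 lower (Kupffer cell markers, sinusoidal endothelial markers and female-biased genes), and 27 lists held genes that changed in either direction. DESeq2 called more members on several lists, among them 9 hepatocyte markers, 10 periportal genes, 10 P450 genes, 6 T and NK cell markers and 6 unfolded protein genes lower, and 6 matrix genes, 6 bile acid genes and 5 immediate early genes higher. With a minimum fold of 1.5, 0 coagulation factors and 0 urea cycle and amino acid genes were lower and 0 immediate early genes higher.

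**Figure D2:**
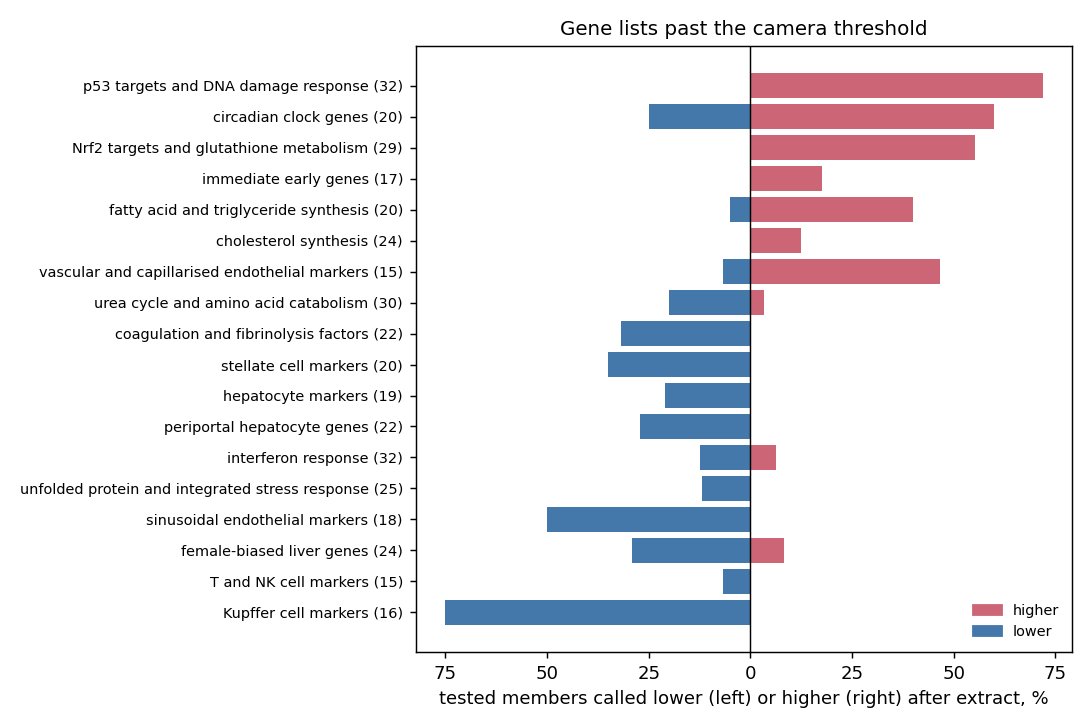
Percentage of tested members that were called higher (red, to the right) or lower (blue, to the left) after the extract, for the 18 gene lists past the camera threshold, with the number of tested members in parentheses. Of the Kupffer cell markers 12 of 16 were lower and 0 higher, and of the p53 targets 23 of 32 were higher and 0 lower.

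By count, the p53 target list showed the most members past the threshold. By share, Kupffer cell markers (12 of 16) and clock genes (12 higher and 5 lower of 20) had more. Of 32 tested p53 targets, 23 rose, 0 fell and 9 did not pass, or 27 higher and 1 lower adjusted over the list alone. The median log2 fold change of the p53 list was 2.23. Tnfrsf10b (6.35), Ddit4l (4.97, a regulator of mTOR signalling) and the exonuclease Aen (2.93) had the smallest p-values after Phlda3. Camera gave an adjusted p of 2.26e-73, and adjusted p = 0.178 with an estimated correlation. The count of higher members ran from 19 without extract replicate 1 to 28 without control replicate 1.

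Many Nrf2 targets and enzymes of glutathione metabolism also rose. Among 29 tested members, 16 were higher, 0 lower and 13 not past the threshold, or 23 higher and 1 lower adjusted over the list alone, with a median of 1.55. The glutathione transferases Gstm3 (4.63), Gstm1 (2.38) and Gstp1 (2.23) and the microsomal epoxide hydrolase Ephx1 (2.45) had the smallest p-values. The Gstm and Gstp genes have close copies that can share reads, so the value of a single member is uncertain. The camera adjusted p was 2.54e-29, and adjusted p = 0.178 with an estimated correlation.

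**Figure D3:**
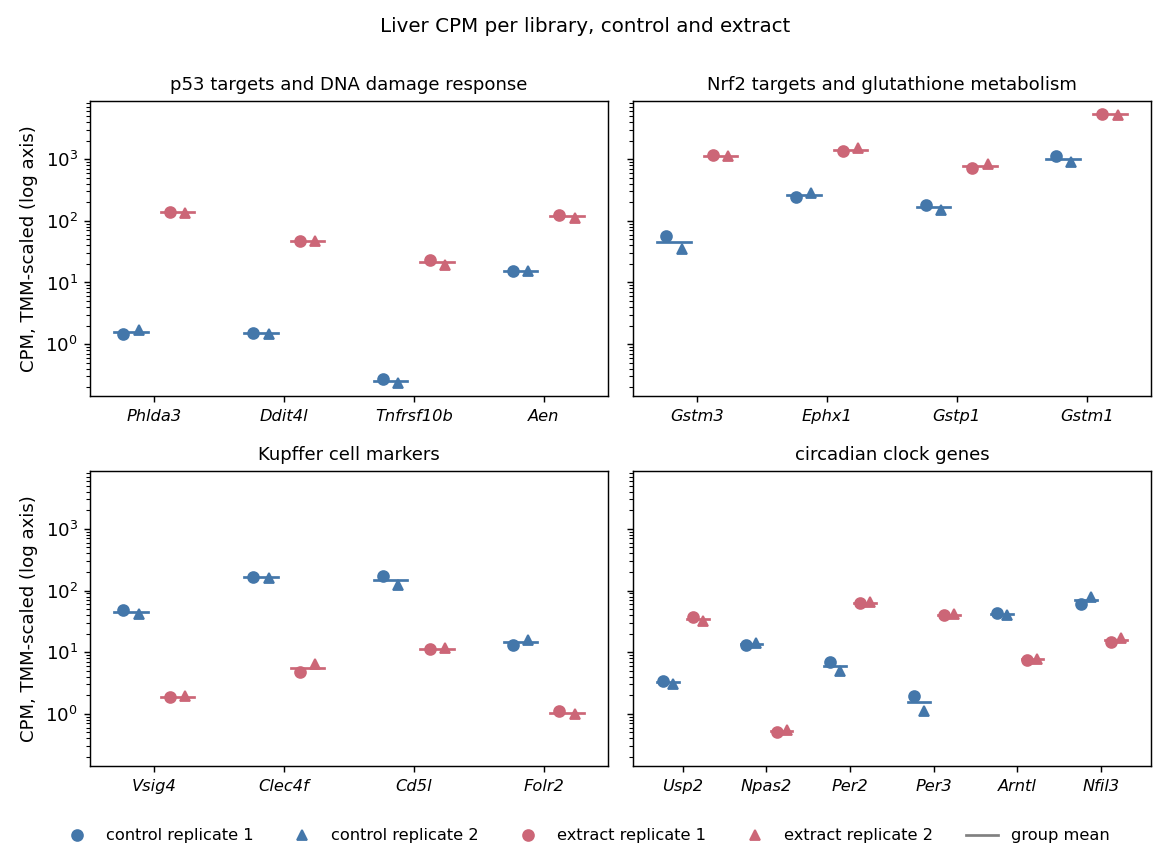
TMM-scaled CPM on a log axis for the members with the smallest p-values in 4 gene lists, in the 2 control (blue) and 2 extract (red) libraries, with horizontal lines for the group means. Phlda3 lies at 1.46 and 1.72 CPM in the control libraries and at 141 and 136 CPM in the extract libraries, and Clec4f at 167 and 160.0 CPM against 4.73 and 6.51 CPM.

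Most Kupffer cell markers fell. Of 16 tested members, 12 were lower, 0 higher and 4 not past the threshold, or 14 lower adjusted over the list alone, and the median was -2.65. Vsig4 and Clec4f, a C-type lectin restricted to Kupffer cells, were followed by Cd5l (-3.67) and the folate receptor Folr2 (-3.77). The camera adjusted p was 1.12e-48, and adjusted p = 0.178 with an estimated correlation. Among monocyte and recruited macrophage markers, 1 of 21 rose, 3 fell and 17 did not pass, with the same counts adjusted over the list alone. Gpnmb rose (3.43), while Fcgr1 (-2.36), Cd68 (-1.28) and lysozyme (Lyz2, -1.11) fell, and the list as a whole had a median of 0.03, which turned to -0.01 under upper-quartile scaling (camera adjusted p = 0.888, adjusted p = 0.968 with an estimated correlation). Without control replicate 1 the monocyte list had 6 members higher and 3 lower with a median of 1.05, and without control replicate 2 it had 3 and 4 with -0.35. Its median was -0.20 with 0 higher and 1 lower without extract replicate 1, and 0.17 with 1 and 1 without extract replicate 2. Fcgr1 and Gpnmb were not past the threshold without extract replicate 1, Lyz2 without extract replicate 2, and Cd68 with either of them left out.

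Several sinusoidal endothelial markers fell as well, while several markers of vascular or capillarised endothelium rose. On the sinusoidal list, 9 of 18 tested members were lower, 0 higher and 9 not past the threshold, or 11 lower adjusted over the list alone, with a median of -0.81. The mannose receptor Mrc1 (-2.25), the hyaluronan receptor Stab2 (-2.01), Gpr182 (-1.87) and the transcription factor Maf (-1.07) had the smallest p-values. Camera gave an adjusted p of 2.24e-08, and adjusted p = 0.178 with an estimated correlation, and 4 members were lower without extract replicate 1. On the vascular list, 7 of 15 members were higher, 1 lower and 7 not past the threshold, with the same counts adjusted over the list alone. Ly6c1 (5.20), endomucin (Emcn, 1.71), caveolin 1 (Cav1, 2.15) and VE-cadherin (Cdh5, 1.11) rose and Plvap (-0.80) fell. The vascular median was 0.13 and the mean 1.20 (camera adjusted p = 0.000874, adjusted p = 0.71 with an estimated correlation), and 1 member was higher without extract replicate 1 and 4 without extract replicate 2. That median was 1.31 without control replicate 1, 0.44 without extract replicate 1, 0.43 without extract replicate 2 and 1.11 under the strict filter on low counts, and 3 members were lower without control replicate 2.

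Some markers of hepatic stellate cells, the pericytes of the sinusoid, fell. Of 20 tested members 7 fell, 0 rose and 13 did not pass, or 10 lower and 1 higher adjusted over the list alone, with a median of -0.54, or -0.28 without control replicate 1. Colec10 (-1.82), Angptl6 (-1.45), Vipr1 (-1.33) and Ecm1 (-1.26) had the smallest p-values. The camera adjusted p was 5.36e-05, and adjusted p = 0.71 with an estimated correlation, with 13 members lower without control replicate 2, 3 without extract replicate 1 and 4 without extract replicate 2. Of 38 extracellular matrix and fibrosis genes, 1 rose, 0 fell and 37 did not pass, with the same counts adjusted over the list alone. The gelatinase Mmp2 rose (4.30-fold), and on the log2 scale Col4a2 (1.53, edgeR adjusted p = 0.0702), Col8a1 (2.18, 0.0953) and lumican (Lum, 0.92, 0.0755) were not past the threshold. The median of that list was 0.14 (camera adjusted p = 0.167, adjusted p = 0.906 with an estimated correlation), but without control replicate 1 there were 15 members higher and a camera adjusted p of 3.62e-07, and without control replicate 2 there were 8 higher and 7 lower, with 0.827. Without extract replicate 2 the matrix list had a camera adjusted p of 0.000438 with 2 members higher. The matrix median changed sign with the libraries used, at 0.91 without control replicate 1, -0.16 without control replicate 2, -0.22 without extract replicate 1 and 0.58 without extract replicate 2.

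Some hepatocyte markers and some coagulation factors fell. Among 19 hepatocyte markers 4 fell, 0 rose and 15 did not pass, or 8 lower adjusted over the list alone, and the median was -0.54. Serpina1c (-1.57), Serpina1a (-1.18), apolipoprotein A1 (Apoa1, -0.87) and fetuin A (Ahsg, -0.75) fell, and the camera adjusted p was 2.89e-06, with adjusted p = 0.646 with an estimated correlation. On the list of 22 coagulation and fibrinolysis factors, 7 were lower, 0 higher and 15 not past the threshold, or 8 lower adjusted over the list alone. Fibrinogen chains Fgg (-1.04) and Fgb (-1.01), alpha-2-antiplasmin (Serpinf2, -0.99) and prekallikrein (Klkb1, -0.94) had the smallest p-values, and the median was -0.28 (camera adjusted p = 0.000459, adjusted p = 0.71 with an estimated correlation). The 7 calls on the coagulation list went to 0 with either extract library left out. Hepatocyte markers had 10 lower without control replicate 1, 7 without control replicate 2, 1 without extract replicate 1 and 2 without extract replicate 2.

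Some periportal genes fell, and pericentral genes had no common direction. Of 22 periportal genes 6 were lower, 0 higher and 16 not past the threshold, or 8 lower adjusted over the list alone, with a median of -0.60. Cathepsin C (Ctsc, -2.00), histidine ammonia-lyase (Hal, -1.95), Hsd17b6 (-1.46) and the polymeric immunoglobulin receptor (Pigr, -0.91) led the list (camera adjusted p = 4.33e-06, adjusted p = 0.282 with an estimated correlation). Its lower members came to 10 without control replicate 1, 11 without control replicate 2, 4 without extract replicate 1 and 3 without extract replicate 2. Of 22 pericentral genes 2 rose, 0 fell and 20 did not pass, or 3 higher and 1 lower adjusted over the list alone. Cyp2a5 (2.62) and the Wnt feedback ligase Rnf43 (0.80) rose, and the list median was -0.03, or 0.15 under total-count scaling (camera adjusted p = 0.527, adjusted p = 0.906 with an estimated correlation). Without control replicate 2 the pericentral list had 7 members higher and 2 lower and a camera adjusted p of 0.00487, and without control replicate 1 it had 2 higher and 6 lower.

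Several genes of fatty acid synthesis rose, and some genes of amino acid catabolism fell. Among 20 genes of fatty acid and triglyceride synthesis 8 were higher, 1 lower and 11 not past the threshold, or 9 higher and 2 lower adjusted over the list alone. The elongase Elovl6 (2.78), fatty acid synthase (Fasn, 1.75), acetyl-CoA carboxylase (Acaca, 1.49) and the regulator Srebf1 (1.26) rose, and Elovl5 (-1.15) fell, with a list median of 0.82 (camera adjusted p = 2.04e-06, adjusted p = 0.489 with an estimated correlation). Its higher members came to 13 without control replicate 2 and 5 without extract replicate 2. Among 24 cholesterol synthesis genes 3 rose, 0 fell and 21 did not pass, with the same counts adjusted over the list alone. Acat2 (1.55) and lanosterol synthase (Lss, 1.09) were among those that rose. The cholesterol median was 0.25 (camera adjusted p = 0.0139, adjusted p = 0.787 with an estimated correlation), and the camera call was lost without control replicate 1 (0.593) and without extract replicate 1 (0.0592), with 16 members higher without control replicate 2 and 1 without extract replicate 1. The cholesterol median was 0.03 without control replicate 1 and 0.63 without control replicate 2. Of 30 genes of the urea cycle and amino acid catabolism 6 were lower, 1 higher and 23 not past the threshold, or 8 lower and 1 higher adjusted over the list alone. Cystathionine beta-synthase (Cbs, -1.05), Agxt (-1.05), Amt (-1.10) and ornithine transcarbamylase (Otc, -0.87) fell and alanine transaminase (Gpt, 0.74) rose. The median of -0.14 turned to 0.03 under total-count scaling (camera adjusted p = 0.00587, adjusted p = 0.71 with an estimated correlation), and the lower members came to 10 without control replicate 1, 2 without extract replicate 1 and 1 without extract replicate 2.

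Core clock genes moved in opposite directions. Of 20 tested members 12 were higher, 5 lower and 3 not past the threshold, or 13 higher and 5 lower adjusted over the list alone. The period genes Per3 (4.68) and Per2 (3.40) and the deubiquitinase Usp2 (3.42) rose, while Npas2, Arntl (-2.42), which encodes Bmal1, and the repressor Nfil3 (-2.15) fell. The median was 1.82 (camera adjusted p = 3.6e-09, adjusted p = 0.394 with an estimated correlation). With either extract library left out 7 members were higher and 3 lower. Among 17 immediate early genes 3 rose, 0 fell and 14 did not pass, or 4 higher adjusted over the list alone, namely Myc (1.34), Jund (0.91) and Ccn1 (0.89) over all genes. Their median was 0.85 (camera adjusted p = 0.00229, adjusted p = 0.753 with an estimated correlation), and without control replicate 2 the camera adjusted p was 0.167. Higher members came to 11 without control replicate 1, 6 without control replicate 2, 1 without extract replicate 1 and 0 without extract replicate 2, and the median to 1.37 and 0.53 without the control libraries in turn.

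Female-biased liver genes were lower in part. Of 24 tested members 7 fell, 2 rose and 15 did not pass, or 9 lower and 2 higher adjusted over the list alone, with a median of -1.21, or -0.74 without control replicate 2. A1bg (-3.61), Sult2a1, Cyp2b13 (-3.36) and Cyp2b9 (-1.57) fell, and Slc16a5 (3.49-fold) and Cyp2a4 (2.46-fold) rose. Camera gave an adjusted p of 4.82e-08, and adjusted p = 0.178 with an estimated correlation. Without control replicate 1 there were 14 lower and 4 higher members, and without control replicate 2 there were 12 and 8. On the male-biased list 5 of 23 rose, 3 fell and 15 did not pass, or 8 higher and 3 lower adjusted over the list alone. Mup20 (3.25) and Gstp1 rose, and Serpina1e, Selenbp2 (-1.27) and C6 (-1.32) fell. The median was -0.41 and the mean -0.38 while camera's direction was upward (camera adjusted p = 0.701, adjusted p = 0.906 with an estimated correlation), and without control replicate 1 it was downward with an adjusted p of 7.66e-10 and 12 members lower. Without control replicate 2 the male-biased median was 0.50.

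Cytochrome P450 and bile acid genes moved both ways. Of 41 tested P450 genes of families 1 to 3, 5 rose, 5 fell and 31 did not pass, or 7 higher and 9 lower adjusted over the list alone. Cyp2a5, Cyp2d9 (1.70) and Cyp2a4 rose, and Cyp2b13, Cyp2c40 (-1.87) and Cyp2b9 fell. The P450 median was -0.15, or 0.05 under total-count scaling and 0.08 without control replicate 2 (camera adjusted p = 0.351, adjusted p = 0.822 with an estimated correlation). Without control replicate 1 there were 9 higher and 16 lower (camera adjusted p = 6.45e-05), without control replicate 2 there were 11 and 12, and with either extract library left out 3 and 3. Many P450 genes have close copies, so reads can be split between neighbours. Of 27 genes of bile acid synthesis and transport, 2 rose, 4 fell and 21 did not pass, or 5 higher and 6 lower adjusted over the list alone. The exporters Abcc4 (3.23) and Abcc2 (0.81) rose, and Cyp8b1, Sult2a8 (-1.87) and Hsd3b7 (-1.37) fell, with a median of -0.12, or 0.05 under total-count scaling and 0.08 without control replicate 2 (camera adjusted p = 0.322, adjusted p = 0.719 with an estimated correlation). Without control replicate 1 there were 9 higher and 8 lower bile acid genes (camera adjusted p = 0.027), without control replicate 2 there were 7 and 8, and without extract replicate 1 there were 1 and 1.

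T and NK cell markers, interferon response genes and genes of the unfolded protein response were lower relative to other genes as lists, with few members past the threshold. Of 15 T and NK cell markers 1 fell, 0 rose and 14 did not pass, or 5 lower adjusted over the list alone, and the median was -2.63 (camera adjusted p = 5.19e-05, adjusted p = 0.719 with an estimated correlation). Granzyme A (Gzma) lay at 7.73 and 1.48 CPM in the control libraries (log2 fold change -3.62, edgeR adjusted p = 0.0551), and Nkg7 at 4.84 and 0.74 CPM (-3.39, 0.0896). Over the members that each fit tested, the median was -1.40 without control replicate 1 and -3.51 without control replicate 2. It was -2.26 without extract replicate 1 and -3.46 without extract replicate 2. Of 32 interferon response genes 4 fell, 2 rose and 26 did not pass, with the same counts adjusted over the list alone. The GTPases Ifi47 (-1.73), Iigp1 (-1.51) and Irgm1 (-0.82) fell and Oasl1 (1.09) and Usp18 (0.79) rose, with a median of -0.60 (camera adjusted p = 0.00337, adjusted p = 0.787 with an estimated correlation). The interferon call was lost without control replicate 1 (0.464, median -0.10), and 23 members were lower without control replicate 2 (median -1.01) and 2 with either extract library left out. Of 25 genes of the unfolded protein and integrated stress response 3 fell, 0 rose and 22 did not pass, or 4 lower adjusted over the list alone. These were Chac1 (-2.59), Dnajb9 (-1.44) and Atf5 (-1.32), with a median of -0.68 (camera adjusted p = 0.00112, adjusted p = 0.753 with an estimated correlation). That call was lost without control replicate 2 (0.115, median -0.19), with 6 members lower and 3 higher. Lower members came to 15 without control replicate 1, 0 without extract replicate 1 and 2 without extract replicate 2.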

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

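The alternatives were planned before the data were examined. Over every alternative scaling, test and filter and every left-out library, 0 of the 1193 called genes turned direction where still tested. Total-count scaling moved the median of all genes by 0.17 on the log2 scale and the share of higher calls from 57.5% to 73.6%, with 940 higher and 338 lower. DESeq2 called 909 genes lower, the minimum fold of 1.5 left 314 higher and 186 lower, and leaving out each library gave 233 to 1826 higher and 134 to 1782 lower, since dropping an extract library leaves the wider control pair to set the spread. Adamts13 passed the threshold by DESeq2 (-1.06) and without a low-count filter (-1.05), and ran from -1.29 to -0.77 over the left-out libraries; the cause was not tested. Lists called went from 7 higher and 11 lower to 0 and 0 with an estimated correlation, and to 2 and 3 by fry, which tests another quantity. The estimate was -0.029 for sinusoidal markers and 0.012 for Nrf2 targets, below or near the fixed 0.01. Their camera calls were lost too, so the correlation between members is not all that differs between the camera settings. The estimated setting also takes its degrees of freedom from the 4 libraries and not from the genes. The platelet list was past no threshold under any alternative, and its median ran from -0.34 to 0.89 over the left-out libraries. Among the 172 named genes, of which 131 were past the threshold, leaving out extract replicate 1 ended 57 calls and extract replicate 2 ended 41, and the minimum fold ended 44. S100a9 ran from -1.79 to 4.63 over the left-out libraries and was called higher without control replicate 1 and lower without control replicate 2, at 3.17 and 0.034 CPM in those libraries; the cause was not tested. Counting depth limits low genes most.

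The same replicate numbers occur in each group, but the labels tie no libraries to a shared animal or batch, and libraries of the same number deviated together with a correlation of 0.157 across genes. With the replicate block edgeR called 902 genes higher and 682 lower, against 686 and 507, and 9 lists higher and 12 lower, with the von Willebrand factor axis (camera adjusted p = 0.0225) and extracellular matrix (0.0314) now among the higher and fatty acid oxidation (0.0191) among the lower, and Adamts13 was at -1.04 (adjusted p = 0.0646), and the platelet median was -0.13.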

Other observations

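The tests of explanations were chosen after the result was seen, except the search for stretches of sequence unique to each Sult2a gene, while the gene lists were fixed before.

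The control libraries differed from each other in liver genes of several kinds, which were named after their values were seen. Control replicate 2 held the major urinary protein gene Mup7 at 126 CPM, the steroid dehydrogenase Hsd3b5 at 56.9 CPM, the elongase Elovl3 at 12.3 CPM and Cyp3a16 at 75.3 CPM, where control replicate 1 held them at 0.48, 0.65, 0.083 and 0.98 CPM. In the extract libraries they lay at 3.11 and 0.44, 0.53 and 0.46, 0.32 and 0.44, and 1.69 and 1.07 CPM. Mup7, Hsd3b5 and Elovl3 are on the male-biased list and Cyp3a16 is on the female-biased list. The male-biased median of -0.41 depended on the control library used, at 0.50 without control replicate 2 and -0.92 without control replicate 1. The lymphatic and sinusoidal gene Lyve1 lay at 47.7 CPM in control replicate 1, 10.5 in control replicate 2, 54.8 in extract replicate 1 and 50.1 in extract replicate 2. The desaturase Scd1 lay at 9198, 3080, 9363 and 11600 CPM. Xist lay between 754 and 1073 CPM in all 4 libraries.

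Lists not described so far had few calls. Of 18 biliary and ductular markers 2 rose (Cd24a, 2.48; Tspan8, 1.81) and 1 fell (Sox9, -1.60), with camera adjusted p = 0.162 and adjusted p = 0.787 with an estimated correlation, and 3 higher and 2 lower adjusted over the list alone. Among 27 acute phase genes 3 rose, Serpina3n (1.83), Socs3 (1.53) and Orm2 (1.23), and 0 fell (camera adjusted p = 0.518, adjusted p = 0.854 with an estimated correlation). Of 23 hypoxia and angiogenesis genes Pfkfb3 (1.70) and P4ha2 (1.60) rose and Ndrg1 (-3.13) and Flt1 (-2.13) fell (camera adjusted p = 0.618, adjusted p = 0.796 with an estimated correlation). Of 21 chemokines, cytokines and adhesion molecules 2 rose, Tnfrsf12a (2.26) and Icam1 (1.20), and 5 fell, among them Ccl24 (-4.48) and Il1b (-2.72), with camera adjusted p = 0.093 and adjusted p = 0.787 with an estimated correlation. Cxcl13 had 240 counts in the control and 3 in the extract libraries, a ratio of 93.5 (95% counting interval 31.6 to 457). Of 34 cell cycle genes cyclin D1 (Ccnd1) rose, with an edgeR adjusted p of 0.0197, and 0 fell (camera adjusted p = 0.407, adjusted p = 0.906 with an estimated correlation), and of 32 fatty acid oxidation genes Cyp4a12a (2.90) rose and 0 fell (camera adjusted p = 0.0817, adjusted p = 0.855 with an estimated correlation). Of 20 complement genes C6 fell and 0 rose (0.407 and 0.787), of 16 heat shock genes Hsph1 (-0.75) fell and 0 rose (0.351 and 0.787), and of 8 mesothelial and adipose markers Krt8 (0.88) rose and Car3 (-1.28) fell (0.151 and 0.71). Of 7 neutrophil, 10 B and plasma cell and 3 erythroid genes tested with edgeR, 0 were past the threshold, with camera adjusted p of 0.888, 0.308 and 0.836. DESeq2 called 1 neutrophil gene higher and 2 lower and 1 B and plasma cell gene lower. Adjusted over the list alone, the higher and lower members numbered 3 and 1 for acute phase genes, 2 and 2 for hypoxia and angiogenesis, 2 and 5 for chemokines, 1 and 0 for the cell cycle, 1 and 0 for fatty acid oxidation, 0 and 1 for complement, 1 and 2 for heat shock genes, and 1 and 1 for mesothelial and adipose markers. Calls on these lists depended on the libraries and on some settings. Without control replicate 1, 18 fatty acid oxidation genes were lower (camera adjusted p = 5.68e-08), 7 cell cycle genes were higher and 3 neutrophil genes were higher. Without control replicate 2, 7 fatty acid oxidation genes were higher and 3 lower, 8 cell cycle genes were lower (0.0376), 6 neutrophil genes were lower (0.0161) and 11 chemokines and cytokines were lower (0.000437). The fatty acid oxidation list was also lower by camera with limma-voom (0.0243) and without extract replicate 2 (0.0154), and the chemokine list with total-count scaling (0.0306). Biliary and ductular markers had 6 higher and 2 lower without control replicate 1 (camera adjusted p = 0.0398), 5 and 2 without control replicate 2, and 0 calls with either extract library left out, where camera called the list higher without extract replicate 2 (0.04). Acute phase genes had 3 higher and 3 lower without control replicate 1, 7 and 6 without control replicate 2, and 3 lower by DESeq2. Hypoxia and angiogenesis genes had 6 higher and 3 lower without control replicate 1 and 5 and 4 without control replicate 2, and heat shock genes 2 and 3, then 2 and 4. With either extract library left out, 2 chemokines and cytokines were lower. Complement genes had 3 lower without control replicate 1, and mesothelial and adipose markers 3 lower without control replicate 2.

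Clock genes of opposite phase moved apart. The 14 genes driven by E-box and D-box elements had a median log2 fold change of 2.86, with 12 higher and 0 lower, and the 6 driven by ROR elements had a median of -1.59, with 0 higher and 5 lower. A different time of day at which the groups were sampled needs such a difference, which was 4.45, and may account for it. An action of the extract on the liver clock cannot be told apart from a difference in time, since the labels give no collection time. Time and group would coincide. The same limit holds for any gene off this list that varies with time of day.

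Most Kupffer cell genes were lower. A share of RNA lower by the same fold in every cell type other than hepatocytes is argued against. The vascular endothelial median lay 2.78 above the Kupffer cell median (95% bootstrap interval over members 1.91 to 5.03). Medians were -0.81 for sinusoidal, -0.54 for stellate, 0.61 for biliary and 0.03 for monocyte markers. For T and NK cell markers the median was -2.63. Several vascular markers rose, which can mask a lower share, so a smaller or uneven fall in share stays open. Scaling is argued against too, since the Kupffer cell median was at most -2.49 under every scaling tried. Fewer Kupffer cells and lower expression per cell cannot be told apart, since the called markers ranged over 4.48 on the log2 scale and some of them are shared with other macrophages.

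Several female-biased genes were lower, among them Sult2a genes, while Sult2a7, singled out after its values were seen, went from 2.66 ± 2.52 to 108 ± 1.14 CPM (edgeR adjusted p = 0.0472). An exchange of reads between near-identical Sult2a genes is argued against, since a median of 88.5% of the 75-base stretches of the tested Sult2a genes, and 100% of those of Sult2a7, occurred in no other gene's transcripts, with 52.8% for Sult2a2 as the lowest, which holds for reads of at least 75 bases, while the read length is not given. The sum of Sult2a1 to Sult2a7, at 162 and 123 CPM in the control and 111 and 112 CPM in the extract libraries (log2 ratio -0.36), moved less than Sult2a1 or Sult2a7 and is what an exchange would also give, though not from reads in unique stretches. RNA of male mice in the extract libraries is argued against, since Y-linked genes had 0 counts there. A shift of all sex-biased genes to the male pattern is argued against, since 5 called genes moved against it (Serpina1e, Selenbp2 and C6 fell, Slc16a5 and Cyp2a4 rose). More called genes moved with it, as 5 male-biased genes rose and 7 female-biased genes fell. A shift of part of the sex-biased genes stays open, with a male-biased median of -0.41 (bootstrap interval -1.28 to 2.23). Cyp2a4 was not checked for reads shared with close copies.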
